A study of Oreochromis niloticus with 12 samples.

How the data were processed

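Gonads of Nile tilapia (Oreochromis niloticus) were compared by RNA sequencing in 12 libraries, with 3 libraries in each of 4 groups: testis control, testis SF1-suppressed, ovary control and ovary SF1-suppressed. SF1 (nr5a1) is a nuclear receptor that activates genes of steroid synthesis in the gonad. Per the labels, antisense RNA fragments against SF1 had been introduced into eggs before fertilisation, and the fish were then kept for 30 days in a small circulating system within a culture of 150 days. The labels name control fish given water and control fish given an empty plasmid, and several antisense constructs, without saying which of them each library came from. They also do not say whether each library came from a separate fish or from pooled tissue. The p-values below therefore measure only the spread between these samples, which may be technical. The strand setting of the libraries, the genome build and the annotation release are not given in the sources used here, so reads from genes that overlap on opposite strands could not be told apart.

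The deposited table held, per the file headers, 12 columns of counts and 12 columns of FPKM for 22283 Ensembl genes, of which 17380 carried a symbol. All 12 columns of each kind were assigned to a library, and 0 value columns were left unmatched. The counts were the authors' expected counts (estimated read counts per gene, whole numbers, not normalised), and they were used as such. The FPKM (fragments scaled for transcript length and library total) were computed by the authors, with a gene at a count of 0 listed at 0.0001 in all cases but 1. HISAT and StringTie were named in the submitters' processing notes, without versions. Genes lay on 1102 scaffolds, whose names are given below as the table gives them. A total of 2070 genes carried a symbol that the annotation shares between several copies. Each is called a copy of that gene here, and its identity and its reads are less certain. Functional terms in the table and the reference annotation were not used here, the latter because it gives another assembly without a link to these scaffolds.

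Total counts ran from 36.8 to 60.5 M per library, so for most genes tested the spread between libraries, not counting error, set the precision. For a group whose 3 libraries were all at 0, fold changes were computed as bounds against 3 counts over the group, which covers counting error only. No other fold change is a bound. Ribosomal RNA genes named in the annotation took at most 8.24e-05% of the counts of a library.

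Genes with an FPKM of at least 1 in at least 3 libraries of a comparison were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling of the library sizes. The p-values were adjusted over all genes tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as past the test. The standard error of a log2 change was derived from its F statistic. The plan had named limma on log2(FPKM + 1) for a table without counts and edgeR for a table with counts. Since the table held counts, edgeR was used, and limma 3.58.1 and DESeq2 1.42.0 were run beside it. Each tissue was fitted on its own 6 libraries, control testis against control ovary on the 6 control libraries, and the difference between the testis change and the ovary change (the interaction) on all 12. SF1 was also compared by an exact two-sided permutation test of the FPKM, which with 3 against 3 libraries cannot give a p under 0.1. Calls shared by the tissues were counted with Fisher's exact test. Changes are given as the libraries labelled SF1-suppressed against control.

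Gene lists were fixed for steroidogenesis, cholesterol synthesis, hormone and growth factor receptors and ligands, Sertoli cells and testis differentiation, Leydig cells, granulosa cells and ovary differentiation, oocytes, liver-made egg proteins, germ cells, meiosis, spermatids and sperm flagella, cell cycle, apoptosis, immediate early and heat shock genes, interferon response, housekeeping genes, the NR5A family, and markers of erythrocytes, leukocytes, stroma and smooth muscle, endothelium, adipocytes, liver, exocrine pancreas and intestine, skeletal muscle, kidney and interrenal tissue, neurons and glia, and mitochondrially encoded genes. Lists with at least 3 tested members were tested with camera from limma with a preset correlation of 0.01 between genes, adjusted over the lists and both tissues. They were tested again with the correlation estimated from the data and with fry. The form with an estimated correlation rests on the few residual degrees of freedom of these libraries and has little power. A call lost with it does not show that the list was unchanged. Of the egg protein list 1 gene was in the table and 0 were tested, and 0 mitochondrially encoded genes were in the table. The NR5A list had 1 tested member in each tissue. The erythrocyte list had 1 in the ovary and the neuron list had 2, so these were not tested there.

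The gene lists, the filter, the comparisons, the thresholds and most alternatives were chosen before the data were examined. So was the rule for the genes named in the text. It took the NR5A family, up to 4 members per list and tissue past the test with the largest change (or, where none passed, the 2 most abundant), the 10 genes per tissue and direction with the largest change among genes whose suppressed libraries all lay to 1 side of the controls and whose higher group averaged at least 5 FPKM, 5 per direction for the tissue difference and the interaction, and every steroidogenesis gene that averaged at least 5 FPKM in a group. Members outside this rule that complete a count of 5 or fewer, and the collagen genes, were chosen after their values were seen. Single results of 3 list members are not reported here, and these members stayed in the counts and list tests. A value of at least 32-fold was used to define switch-like differences after the data had been seen.

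The procedure was tested on simulated data, with 200 changed genes at a time. These data used the mean of each gene over all libraries of a comparison, and the fitted dispersions. For the control tissues and the interaction, testis and ovary were thus averaged, so those shares come from data without the tissue difference. At a fold of 2, edgeR recovered 58.5% of them in testis, 82% in ovary, 70.5% between control tissues and 31% in the interaction. At a fold of 1.5 it recovered 0% in testis and 65% in ovary, and at a fold of 4 it recovered 96.5% and 98%. The data held more calls (1571 in testis and 4510 in ovary), which eases the adjusted threshold. The simulation also gave both labels the same spread, while the common coefficient of variation was 22.6% in suppressed and 13.0% in control testis. These shares are therefore not the power in the real data. The share of false calls reached 12.2%, above the nominal level, so single genes near the threshold are less certain than their adjusted p. At a fold of 2 the share of false calls was between 16.7 and 32.1% for DESeq2 and between 4.26 and 7.59% for limma.

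Alternatives were median-of-ratios scaling, scaling by total count, quantile normalisation, another pseudocount, no filter and a filter at an FPKM of 5, weights per library, no mean-variance trend, a block for the replicate number, 1 fit over all 12 libraries, a minimum absolute log2 change of 1, and leaving out each library in turn. Quantile normalisation, the other pseudocount, the weights per library and the fit without a trend were run with limma on log2 FPKM. Set against edgeR, they therefore change the tool, the values and the scaling as well as the named setting. The FPKM filter was applied again in each fit without 1 library. A gene above it only in the 3 libraries of 1 group was then not tested without any of them. Its list lost that member, which by itself could change the call of the list. Scaling by total count shifted the median log2 change of all genes to -0.12 in testis, -0.08 in ovary and 0.24 between control tissues, and changes below are relative to TMM scaling.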

Results

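RNA levels were measured in testis and ovary of Nile tilapia labelled control or SF1-suppressed, with 3 libraries in each of the 4 groups. The testis control libraries (replicates 1, 2 and 3) held 37.6, 51.2 and 36.8 M counts, and the testis libraries labelled SF1-suppressed held 56.6, 48.4 and 47.3 M. The ovary control libraries held 49.5, 51.7 and 57.2 M counts, and the ovary libraries labelled SF1-suppressed held 53.0, 58.9 and 60.5 M. The first principal component of all libraries (83.7% of the variance) separated testis from ovary. On the second (5.88%), the 6 libraries labelled SF1-suppressed had positive values, from 16.8 to 63.2, and the 6 control libraries had negative ones. Suppressed testis replicate 3 stood apart from its group: its biological coefficient of variation was 28.2% against replicate 1 and 25.1% against replicate 2, while replicates 1 and 2 differed by 12.7%. The 10 most abundant genes took between 5.14 and 5.4% of the counts in suppressed testis and between 3.73 and 3.93% in control testis.

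The comparison of control with SF1-suppressed libraries asked what antisense RNA against SF1, given to the egg, left changed in the gonads of grown fish. The target itself, nr5a1 (ENSONIG00000020218, scaffold GL831302.1, from base 867944 to base 883455), averaged 18.1 ± 10.2 FPKM in suppressed testis and 13.0 ± 4.42 in control testis (SD, n = 3). The suppressed libraries stood at 23.7, 24.3 and 6.34 FPKM and the control libraries at 9.26, 11.8 and 17.9. The log2 change was 0.58 (SE 0.44, adjusted p = 0.415; exact two-sided permutation p = 0.4, where the smallest possible is 0.1). Without suppressed replicate 3 it was 0.97 (adjusted p = 0.00613), that is, higher in the libraries labelled SF1-suppressed. In ovary nr5a1 averaged 2.01 ± 0.834 FPKM in suppressed and 2.04 ± 0.718 in control libraries, a log2 change of 0.04 (SE 0.34, adjusted p = 0.935; exact permutation p = 0.9). SF1 RNA therefore went against the label in 2 of the 3 suppressed testis libraries, and every direction below is between labels, not between measured levels of SF1. Its relatives nr5a2 and nr5a5 averaged under 1 FPKM in each group. In testis nr5a2 had 0.149 ± 0.0685 FPKM in suppressed and 0.330 ± 0.0992 in control libraries (exact permutation p = 0.2), and nr5a5 had 0.101 ± 0.0447 and 0.270 ± 0.0794 (exact permutation p = 0.1). In ovary nr5a2 had 0.244 ± 0.0558 and 0.509 ± 0.116 FPKM (exact permutation p = 0.1), and nr5a5 was listed at 0 counts in all 6 libraries.

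In the testis libraries labelled SF1-suppressed, the steroidogenesis and cell cycle lists were higher (camera adjusted p = 0.00521 and 8.92e-06). Both calls were lost with an estimated correlation (adjusted p = 0.675 and 0.765) and with fry (adjusted p = 0.0679 and 0.0957). Among 21 Sertoli cell genes 1 rose and 3 fell. The RNA of star, which carries cholesterol into mitochondria as the first step of steroid synthesis, averaged 698 ± 314 FPKM in suppressed and 255 ± 53.0 in control testis (SD, n = 3; log2 change 1.55, SE 0.32, adjusted p = 0.0232). Clusterin (clu), a secreted chaperone, fell by 2.99 on the log2 scale, from 243 ± 16.6 to 28.0 ± 3.68 FPKM (SE 0.16, adjusted p = 0.000117). The Sertoli cell factor sox9a rose from 2.61 ± 0.136 to 10.4 ± 1.53 FPKM. Of 14368 genes tested, 755 were higher and 816 were lower in the libraries labelled SF1-suppressed. The groups did not overlap for 5597 genes (39.0%, where chance gives 10%).

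Of 28 tested genes of steroidogenesis, 5 rose, 0 fell and 23 did not pass the test, and 6 rose when adjusted over the list alone. The list as a whole was higher (median log2 change 0.44, camera adjusted p = 0.00521; adjusted p = 0.675 with an estimated correlation). Besides star, hsd3b1, which makes progesterone and androstenedione, rose from 122 ± 16.6 to 324 ± 129 FPKM. The gene hsd11b2, which acts on cortisol and 11-oxygenated androgens, rose from 55.7 ± 13.1 to 175 ± 94.9. A copy of the steroid 5-beta-reductase AKR1D1 (ENSONIG00000009750) rose from 1.89 ± 0.400 to 6.56 ± 1.32 FPKM, and a copy of the nuclear receptor NR4A1 rose from 3.30 ± 0.412 to 5.38 ± 0.553. The side-chain cleavage enzyme cyp11a2 stood at 338 ± 175 against 192 ± 44.0 FPKM (adjusted p = 0.156; 0.0449 with DESeq2) and cyp11c1, of 11-ketotestosterone synthesis, at 24.5 ± 14.0 against 15.1 ± 1.54 (adjusted p = 0.232). The hydroxylase cyp17a2 stood at 180.1 ± 141 against 357 ± 128 FPKM (adjusted p = 0.447), with 239, 282 and 19.3 in the 3 suppressed libraries. With DESeq2 a copy of cbr1, a copy of hsd11b1la, scarb1 and fdx1 also passed (adjusted p from 0.0286 to 0.0383). In suppressed replicate 3 star was at 336 FPKM, against 889 and 871 in replicates 1 and 2. Without that library 10 members of the list rose and star had an adjusted p of 5.47e-06. Without any 1 of the other 5 libraries between 1 and 3 members passed, and star did not (adjusted p up to 0.131). The calls of hsd11b2 (up to 0.156 without any library but suppressed replicate 3) and hsd3b1 (up to 0.0887, lost without any control library or suppressed replicate 2) were also lost in fits without 1 library. That of NR4A1 was lost without control replicate 1, control replicate 3 or suppressed replicate 2 (up to 0.0627).

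**Figure D1:**
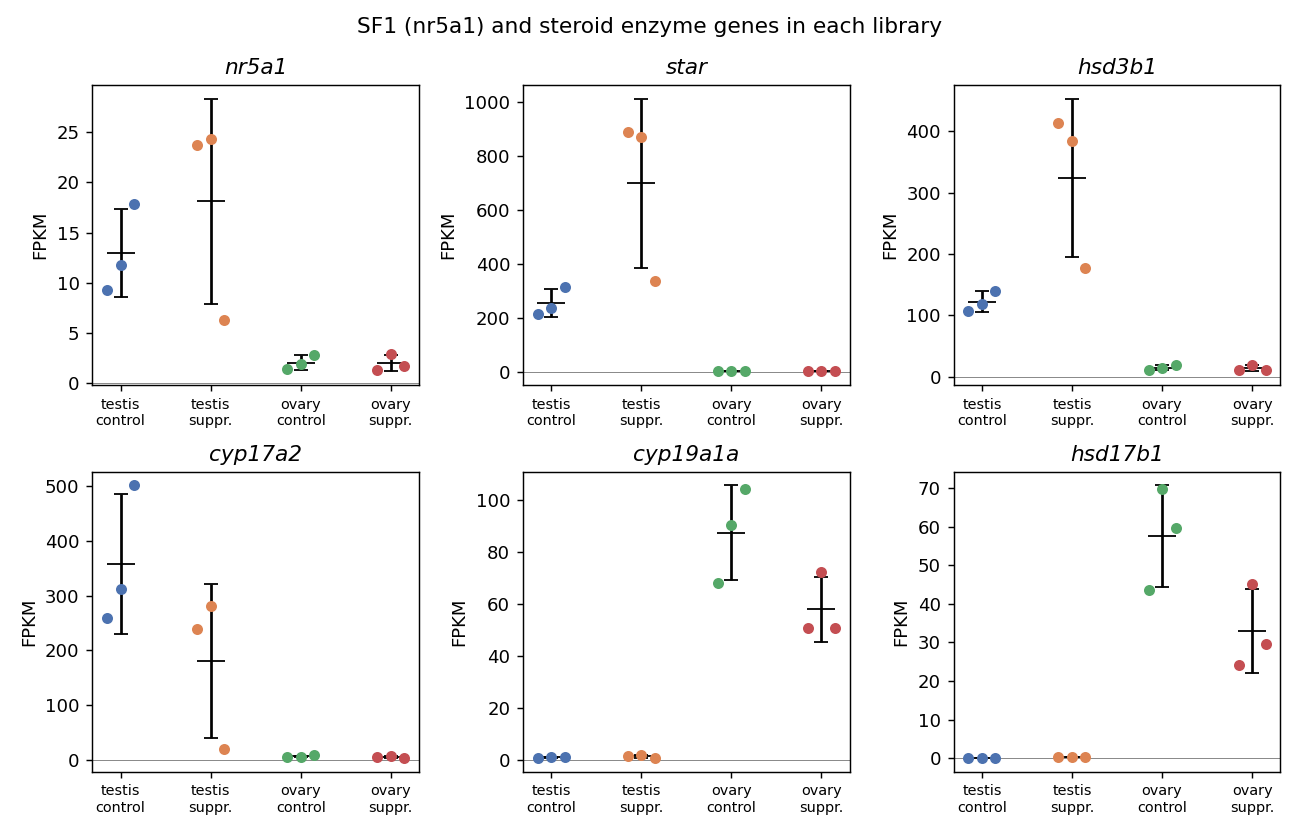
FPKM of nr5a1, star, hsd3b1, cyp17a2, cyp19a1a and hsd17b1 in each library (points), by tissue and label, with bars at the mean and whiskers for the SD (n = 3). In suppressed testis star lay at 889 and 871 FPKM in replicates 1 and 2 and at 336 in replicate 3, and nr5a1 at 23.7, 24.3 and 6.34.

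Of 13 Leydig cell genes, 3 rose (star, hsd3b1 and hsd11b2, also counted above), 0 fell and 10 did not pass. The counts were the same when adjusted over the list alone, and the list was not past its test (median 0.61, adjusted p = 0.208). Its median lay 1.06 and 1.17 log2 units above the control mean in suppressed replicates 1 and 2 and at -0.35 in replicate 3. Without replicate 3, 6 members rose and 1 fell and the list had an adjusted p of 4.7e-09 (adjusted p = 0.619 with an estimated correlation). Without any 1 other library at most 1 member passed. Stroma and smooth muscle genes followed the same split, with medians of 1.24, 0.70 and -1.39 in the 3 suppressed libraries. Of 27 tested, 2 rose, 1 fell and 24 did not pass, as when adjusted over the list alone (list median 0.40, adjusted p = 0.199). The matrix genes dcn (decorin, from 105 ± 13.2 to 272 ± 61.0 FPKM) and mgp (from 2.1 ± 0.398 to 9.65 ± 1.98) rose, and postna fell from 2.27 ± 0.0471 to 1.15 ± 0.163. The calls of dcn and mgp held when any 1 library was left out, and that of postna was lost without any library but suppressed replicate 3 (adjusted p up to 0.134). Leaving out suppressed replicate 3, 14 stroma genes rose and 2 fell and the list had an adjusted p of 2.79e-12 (adjusted p = 0.619 with an estimated correlation). Without control replicate 3 it had one of 0.0433 (adjusted p = 0.936 with an estimated correlation).

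Of 4 cholesterol synthesis genes that rose among 26 tested (0 fell and 22 did not pass; 5 rose when adjusted over the list alone), fdft1, the squalene synthase, went from 4.19 ± 0.0152 to 8.95 ± 0.336 FPKM, and the others were the lipoprotein receptor genes ldlra and ldlrb and the mevalonate pathway enzyme pmvk. The list was not past its test (median 0.13, adjusted p = 0.0644). Only fdft1 kept its call without each library in turn, and 1 or 2 members passed without any 1 library other than suppressed replicate 3. The call of ldlrb was also lost under scaling by total count (adjusted p = 0.0759).

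Among 21 Sertoli cell and testis differentiation genes, 1 rose, 3 fell and 17 did not pass, and 3 rose and 4 fell when adjusted over the list alone. The list was lower (median -0.45, adjusted p = 0.0463; adjusted p = 0.675 with an estimated correlation), and its test was lost without suppressed replicate 3 (adjusted p = 0.246) and under median-of-ratios scaling (0.0516). Without that replicate 3 members rose and 4 fell. Besides clu, the tight junction genes tjp1b (from 96.3 ± 3.81 to 34.6 ± 2.22 FPKM) and cldn11a (from 161 ± 18.1 to 99.5 ± 10.2) fell. The calls of clu, sox9a and tjp1b held when any 1 library was left out; that of cldn11a was lost without control replicate 2, control replicate 3 or suppressed replicate 2 (adjusted p up to 0.0914). The median of the list lay at -0.10, -0.26 and -0.67 in the 3 suppressed libraries. Of 10 granulosa cell genes, RUNX1 rose, rspo2 fell and 8 did not pass (2 rose and 1 fell when adjusted over the list alone; list median 0.10, adjusted p = 0.799). Of 27 hormone and growth factor receptors and ligands, 1 rose, the activin receptor ACVR1, and 26 did not pass (0 when adjusted over the list alone; list median -0.33, adjusted p = 0.181). Without suppressed replicate 3, 3 granulosa genes rose and 1 fell and 3 genes of the receptor list rose and 3 fell. Without any 1 other library between 0 and 2 granulosa genes passed and 0 of the receptor list. The calls of RUNX1, rspo2 and ACVR1 were lost without control replicate 1 or 2 or suppressed replicate 2, among others (adjusted p up to 0.181, 0.109 and 0.184), and those of RUNX1 and ACVR1 under scaling by total count (0.0738 and 0.114).

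Of 47 cell cycle genes in suppressed testis, 9 rose, 1 (prc1b) fell and 37 did not pass, and 23 rose and 1 fell when adjusted over the list alone. The list was higher (median 0.39, adjusted p = 8.92e-06; adjusted p = 0.765 with an estimated correlation) and stayed past its test without each library in turn. Its median was 0.31, 0.23 and 0.57 in the 3 suppressed libraries. The replication genes pcna (from 139 ± 14.8 to 232 ± 14.9 FPKM), rrm1 (from 73.7 ± 2.90 to 116 ± 5.78) and ccne2 (from 8.57 ± 0.386 to 13.8 ± 0.733) were among them. The calls of rrm1 and ccne2 held without each library in turn, and that of pcna was lost without control replicate 2 or 3 (adjusted p up to 0.0735). With suppressed replicate 3 left out, 19 members rose and 1 fell, and without any 1 other library between 2 and 5 passed. Of 26 germ cell genes, ddx4 (vasa), an RNA helicase of the germ line, rose from 499 ± 41.4 to 882 ± 86.9 FPKM, 3 fell (dnd1, taf4b and NANOS2) and 22 did not pass, as when adjusted over the list alone (list median -0.01, adjusted p = 0.937). The spermatogonial NANOS2 went from 13.5 ± 1.92 to 5.58 ± 1.39 FPKM. The call of ddx4 was lost without control replicate 2 (adjusted p = 0.0633). Those of dnd1, taf4b and NANOS2 were lost without control replicate 1 or 2 or suppressed replicate 2, among others (up to 0.0730, 0.0645 and 0.148). Without control replicate 1 or 2 or suppressed replicate 2, 1, 0 and 1 germ cell genes passed, and 6 did without suppressed replicate 3.

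The meiosis list was higher by its test (32 tested; 1 rose, rec8b, 1 fell, cyp26a1, and 30 did not pass; 0 when adjusted over the list alone; median 0.23, adjusted p = 0.0494; adjusted p = 0.765 with an estimated correlation). That call was lost under median-of-ratios scaling (0.0532), without any 1 control library and without suppressed replicate 3 (adjusted p up to 0.117). Those of rec8b and cyp26a1 were lost without any library but suppressed replicate 3 (up to 0.179 and 0.155), without which 5 members passed. Of 91 spermatid and sperm flagellum genes, 2 rose (dnah1 and dcst2), 1 fell (ak7b) and 88 did not pass, with 1 rise when adjusted over the list alone (median 0.02, adjusted p = 0.932). The axonemal dynein dnah1 went from 8.29 ± 0.454 to 23.5 ± 1.39 FPKM and kept its call without each library in turn. Those of dcst2 and ak7b were lost without any 1 control library or suppressed replicate 2 (adjusted p up to 0.141 and 0.136), each leaving 1 member past the test. Without suppressed replicate 3, in which the list had a median of 0.26 against -0.24 and -0.04 in replicates 1 and 2, 16 members fell and 3 rose. Of 19 oocyte genes 0 passed (median 0.17, adjusted p = 0.505). The most abundant were tdrd5, at 182 ± 8.21 against 188 ± 13.1 FPKM, and figla, at 44.8 ± 6.62 against 41.3 ± 2.45.

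Of 39 immediate early and heat shock genes, 6 fell, 2 rose (NR4A1 and a copy of HSPA5) and 31 did not pass; 9 fell and 4 rose when adjusted over the list alone (list median -0.09, adjusted p = 0.240). The transcription factor genes fosab (from 3.45 ± 0.355 to 0.915 ± 0.328 FPKM) and jun (from 38.0 ± 1.06 to 13.0 ± 3.28) fell, and kept their calls without each library in turn. With suppressed replicate 3 left out, 9 members fell and 7 rose, and without any 1 control library or suppressed replicate 2 between 3 and 4 passed. Among 19 housekeeping genes, ACTB fell from 49.5 ± 8.74 to 17.9 ± 1.08 FPKM and gapdh from 261 ± 11.9 to 109 ± 20.3. The genes sdha and rplp0 rose and 15 did not pass, as when adjusted over the list alone (median 0.17, adjusted p = 0.717). The rise of rplp0 was lost under scaling by total count (adjusted p = 0.0586) and without any library but suppressed replicate 3 (up to 0.191), and that of sdha without any 1 control library (up to 0.113), each leaving 2 members past the test.

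Some markers of other organs also moved in suppressed testis. Most members of these lists in the table did not meet the FPKM filter. In testis 6 of 30 liver, 3 of 15 exocrine pancreas and intestine, 12 of 26 skeletal muscle and 9 of 19 kidney and interrenal markers were tested. The counts below cover only these and do not measure the amount of another organ's tissue. Of 6 liver markers, 3 fell (apoeb, ambp and c8a), 0 rose and 3 did not pass, while 1 rose and 3 fell when adjusted over the list alone (median -0.77, adjusted p = 0.0335; adjusted p = 0.675 with an estimated correlation). Of 3 exocrine pancreas and intestine markers, the digestive enzyme genes cpa1 (from 34.5 ± 6.93 to 9.94 ± 3.65 FPKM) and try (from 1.92 ± 0.408 to 0.0498 ± 0.0861) fell, as when adjusted over the list alone (median -1.69, adjusted p = 0.0114; adjusted p = 0.578 with an estimated correlation). Of 12 skeletal muscle markers, 4 rose (acta1a, a copy of ACTC1, pvalb4 and eno3), 1 fell (mybpc1) and 7 did not pass, and 6 rose and 1 fell when adjusted over the list alone (median 0.61, adjusted p = 0.0420; adjusted p = 0.578 with an estimated correlation). The sarcomeric actin acta1a stood at 76.9 ± 61.7 against 6.38 ± 2.45 FPKM, a rise that was lost without any 1 control library or suppressed replicate 2 (adjusted p up to 0.0986). The liver list lost its call without any 1 control library or suppressed replicate 1 (adjusted p up to 0.307), and the muscle list without suppressed replicate 1 or 2 (up to 0.141). The FPKM filter was applied anew in these fits, so a marker above it only in control libraries dropped out without 1 of them. The liver list could lose members that way. The pancreas list could be tested in only 3 of these fits, those without a suppressed library, where it kept its call. Without any 1 control library 0 muscle markers and 1 liver marker passed, and without suppressed replicate 1 or 2 1 muscle marker did. Markers that fell below the filter in such a fit are not among those that passed, so these counts do not show lost significance alone. The calls of ACTC1, pvalb4 and mybpc1 (adjusted p up to 0.176, 0.0850 and 0.0701) and of c8a (up to 0.0671) were among those lost, and that of ACTC1 was also lost under scaling by total count (0.0558). Of 9 kidney and interrenal markers, the sulphate transporter slc26a1 rose from 5.17 ± 0.300 to 36.9 ± 2.11 FPKM, lrp2b and nphs1 fell and 6 did not pass (2 rose and 3 fell when adjusted over the list alone). Their median was -0.18, while the mean of 0.10 and the test were positive (adjusted p = 0.259). The calls of lrp2b and nphs1 were lost without suppressed replicate 1 or 2, among others (up to 0.0913 and 0.192), and with an adjusted p of 0.0431 the list passed without control replicate 3 (adjusted p = 0.704 with an estimated correlation).

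Beyond the lists, the largest changes in testis included genes near 0 on 1 side. A copy of LSM3 (ENSONIG00000000370) averaged 30.5 ± 5.25 FPKM in suppressed and 0.0562 ± 0.0971 in control testis. Also, 2 copies of cyp4f3, a fatty acid hydroxylase, rose to 22.1 ± 2.43 and 40.3 ± 4.09 FPKM from 1.74 ± 0.272 and 3.27 ± 0.679. Among genes that fell, zgc:110333 averaged 7.08 ± 0.866 FPKM in control testis and was listed at 0 counts in all 3 suppressed libraries, at least 331-fold lower. A copy of the chemotactic factor LECT2 fell from 95 ± 13.0 to 3.68 ± 0.556 FPKM, and ch25h, which makes 25-hydroxycholesterol, from 5.80 ± 1.25 to 0.579 ± 0.0244. These calls held in every fit that tested them. For LSM3, zgc:110333 and ch25h, under 1 FPKM in the lower group, those fits left out only libraries of that group. The libraries behind their high level were thus never left out. The number of testis genes changed moved with single libraries: 447, 312 and 427 genes passed without control replicate 1, 2 or 3, and 1058, 611 and 2790 without suppressed replicate 1, 2 or 3. Under scaling by total count 554 genes were higher and 1183 lower.

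**Figure D2:**
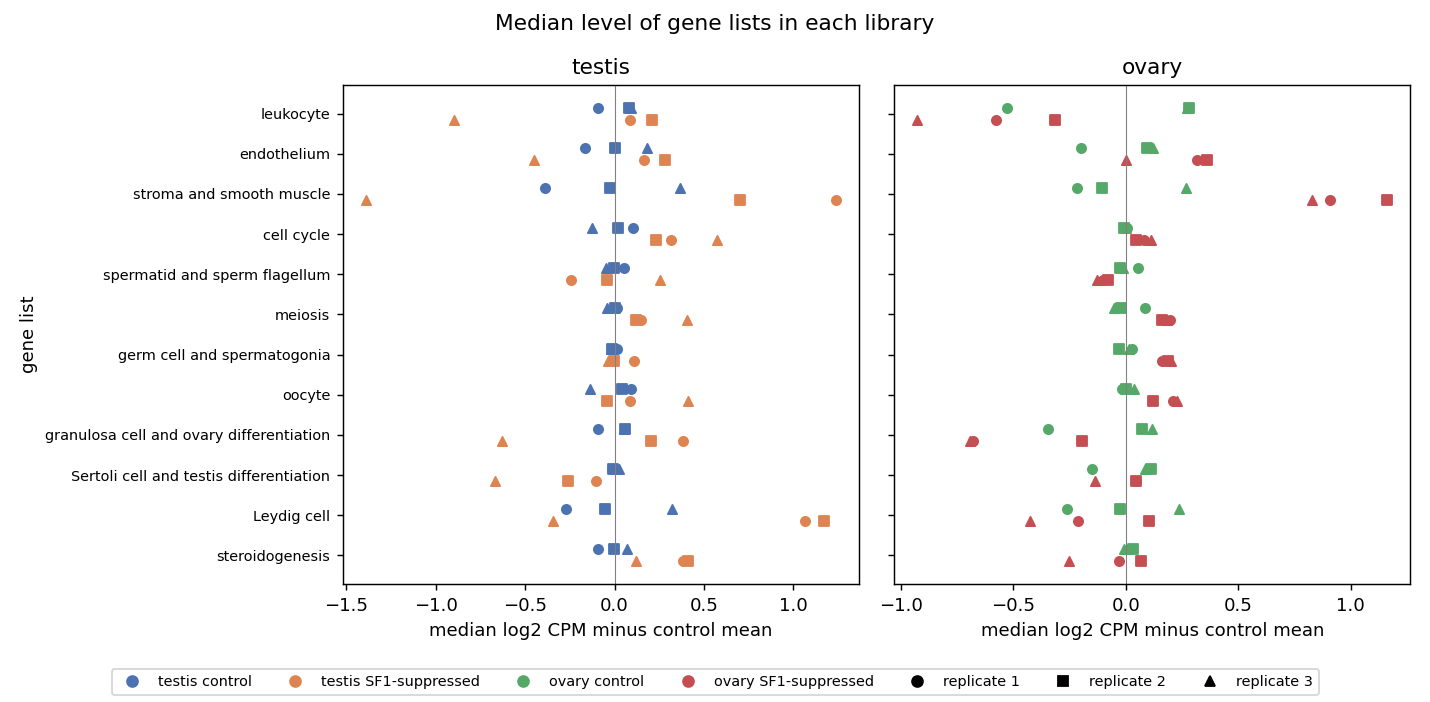
Median log2 CPM of 12 gene lists in each library, minus the mean of the control libraries, for testis and ovary (colours for labels, shapes for replicates). In suppressed testis the Leydig cell list lay at 1.06, 1.17 and -0.35 and the stroma list at 1.24, 0.70 and -1.39, while in suppressed ovary the stroma list lay at 0.91, 1.16 and 0.83.

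In the ovary libraries labelled SF1-suppressed, the germ cell, oocyte and stroma lists were higher (camera adjusted p = 0.00521, 0.0420 and 5.8e-06), calls lost with an estimated correlation (adjusted p = 0.578, 0.749 and 0.675). Of 13 granulosa cell genes 6 fell. The germ line helicase ddx4 (ENSONIG00000012063, scaffold GL831144.1, from base 2765308 to base 2772207) rose from 151 ± 3.29 to 369 ± 1.75 FPKM (SD, n = 3; log2 change 1.36, SE 0.05, adjusted p = 5.66e-08). Decorin (dcn) rose from 7.98 ± 0.975 to 20.7 ± 4.55 FPKM. Aromatase (cyp19a1a), which makes oestradiol, fell from 87.3 ± 18.2 to 57.8 ± 12.5 FPKM (log2 change -0.53, SE 0.16, adjusted p = 0.0317). Of 12557 genes tested, 2268 were higher and 2242 were lower, and the groups did not overlap for 6282 genes (50%, where chance gives 10%).

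Of 29 steroidogenesis genes in ovary, 6 rose, 8 fell and 15 did not pass, as when adjusted over the list alone (list median -0.04, adjusted p = 0.836). Lower were a copy of the carbonyl reductase cbr1 (from 30.7 ± 4.93 to 4.53 ± 1.48 FPKM), cyp11c1 (from 14.8 ± 2.12 to 7.22 ± 0.875), hsd17b12a (from 27.5 ± 0.835 to 14.7 ± 2.18) and hsd17b1, which reduces oestrone to oestradiol (from 57.6 ± 13.1 to 33.0 ± 10.9). Higher was hsd3b7, of bile acid synthesis, from 104 ± 1.45 to 205 ± 4.19 FPKM. The calls of cyp19a1a and hsd17b1 were lost without control replicate 2 or 3 or suppressed replicate 1 or 3 (adjusted p up to 0.120 and 0.0875) and with DESeq2 (0.0730 and 0.0604), and that of tspo without control replicate 3 or suppressed replicate 1 or 3 (up to 0.0907) and under scaling by total count (0.0852). Without suppressed replicate 1, 9 members of the list passed. Of 9 Leydig cell genes, 1 fell (cyp11c1) and 8 did not pass, as when adjusted over the list alone (median -0.07, adjusted p = 0.560).

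Of 13 granulosa cell and ovary differentiation genes, 0 rose, 6 fell and 7 did not pass, as when adjusted over the list alone, and the list was not past its test (median -0.53, adjusted p = 0.161). The signalling genes rspo1 (from 1.20 ± 0.131 to 0.437 ± 0.0426 FPKM), kitlga (from 3.24 ± 0.365 to 1.85 ± 0.132) and wnt4a (from 4.14 ± 1.32 to 2.26 ± 0.389) were among those that fell. The call of wnt4a was lost without control replicate 2 or 3 or suppressed replicate 1 or 3 (adjusted p up to 0.0962), and 2 or 3 members passed without any 1 of these 4. Of 19 Sertoli cell and testis differentiation genes, dmrt1, a male sex determination factor, rose from 1.04 ± 0.269 to 3.25 ± 0.0654 FPKM, amh rose, 5 fell (among them sox8a, dmrt2a and cldn11a) and 12 did not pass (3 rose and 5 fell when adjusted over the list alone). The list had a median of 0.00198, a mean of -0.09 and a negative test (adjusted p = 0.666). In control testis dmrt1 stood at 268 ± 9.58 FPKM.

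Of 20 cholesterol synthesis genes in ovary, 8 fell, 1 rose (mvk) and 11 did not pass, as when adjusted over the list alone (list median -0.16, adjusted p = 0.136). The lipoprotein receptor ldlra fell from 16 ± 1.39 to 6.25 ± 0.417 FPKM and insig1 from 10.2 ± 1.38 to 5.10 ± 0.509. Without suppressed replicate 1, 5 members passed, and without control replicate 3 the list had an adjusted p of 0.0406 (adjusted p = 0.643 with an estimated correlation). Of 23 hormone and growth factor receptors and ligands, 6 rose, 4 fell and 13 did not pass, as when adjusted over the list alone, with a median of -0.13, a mean of 0.03 and a positive test (adjusted p = 0.711). The activin subunit inhbaa rose from 0.953 ± 0.475 to 6.21 ± 0.293 FPKM, while a copy of ACVR2B fell from 3.94 ± 0.0934 to 1.95 ± 0.302.

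Of 22 oocyte genes, 12 rose, 0 fell and 10 did not pass, and 14 rose when adjusted over the list alone. The list was higher (median 0.19, adjusted p = 0.0420; adjusted p = 0.749 with an estimated correlation), and its test was lost without control replicate 1 or 2 (adjusted p up to 0.0598), and 8 members passed without suppressed replicate 1 or 3. The maternal effect gene zar1 went from 955 ± 73.6 to 1249.5 ± 3.17 FPKM, the RNA binding YBX2 from 100.2 ± 7.73 to 132 ± 4.87 and figla, an oocyte transcription factor, from 21.1 ± 0.202 to 24.8 ± 1.67. Of 20 germ cell genes, 8 rose, 1 fell (itga6a) and 11 did not pass, as when adjusted over the list alone. The list was higher (median 0.16, adjusted p = 0.00521; adjusted p = 0.578 with an estimated correlation) without each library in turn. Besides ddx4, dnd1 rose from 65.3 ± 2.76 to 88.8 ± 1.97 FPKM and tdrd9 from 7.80 ± 1.23 to 11 ± 0.960. The fall of itga6a was lost without control replicate 3 or suppressed replicate 1 or 3 (adjusted p up to 0.0533). Of 19 housekeeping genes 7 rose, 0 fell and 12 did not pass, as when adjusted over the list alone (median 0.13, adjusted p = 0.0692). A copy of GAPDH went from 1122.7 ± 33.2 to 1498.9 ± 19.7 FPKM. That list had an adjusted p of 0.0339 without control replicate 2 and of 0.0334 and 0.0375 without suppressed replicate 2 or 3 (adjusted p = 0.665, 0.597 and 0.709 with an estimated correlation), and 4 members passed without suppressed replicate 1.

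Of 25 meiosis genes in ovary, 11 rose, 6 fell and 8 did not pass, with 13 and 6 when adjusted over the list alone (median 0.19, adjusted p = 0.240). A copy of the nuclear envelope gene SUN1 rose from 55.5 ± 1.59 to 123.4 ± 8.41 FPKM and aldh1a2, which makes retinoic acid, from 1.48 ± 0.450 to 3.63 ± 1.03. The recombinase dmc1 fell from 12.2 ± 0.366 to 5.55 ± 0.792 FPKM and the synaptonemal complex gene sycp3 from 6.63 ± 0.576 to 3.14 ± 0.965. Without suppressed replicate 3, 10 members passed. Of 42 flagellum genes, 11 fell, 6 rose and 25 did not pass, as when adjusted over the list alone (median -0.12, adjusted p = 0.161). The flagellum gene CFAP69 fell from 10.8 ± 1.22 to 1.29 ± 0.120 FPKM and ttc25 from 6.53 ± 0.845 to 0.988 ± 0.0614. Of 48 cell cycle genes, 18 rose, 5 fell and 25 did not pass, with 21 and 5 when adjusted over the list alone (median 0.04, adjusted p = 0.136). Survivin (birc5b) went from 731 ± 23.8 to 1012.9 ± 6.72 FPKM and rrm1 from 70.4 ± 0.932 to 106 ± 2.46. Without suppressed replicate 2 that list had an adjusted p of 0.0215 (adjusted p = 0.479 with an estimated correlation). Of 35 immediate early and heat shock genes, 9 rose, 5 fell and 21 did not pass, with 10 and 5 when adjusted over the list alone (median 0.08, adjusted p = 0.442). The stress gene ddit4 rose from 0.451 ± 0.0870 to 5.93 ± 2.05 FPKM, and dusp2 fell from 1.51 ± 0.153 to 0.503 ± 0.132. Without suppressed replicate 1, 9 members of that list passed.

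Stroma and smooth muscle genes rose in suppressed ovary: of 28, 21 rose, 2 fell (myh11b and a copy of PDGFRB) and 5 did not pass, and 22 rose and 2 fell when adjusted over the list alone. The list was higher (median 0.87, adjusted p = 5.8e-06; adjusted p = 0.675 with an estimated correlation) without each library in turn, with medians of 0.91, 1.16 and 0.83 in the 3 suppressed libraries. The matrix genes thbs2a (from 0.465 ± 0.0585 to 3.33 ± 1.05 FPKM) and fn1b, a fibronectin (from 1.82 ± 0.949 to 10.4 ± 3.92), rose, as did the collagens col1a1, col1a1b and col1a2 (log2 changes 1.75, 1.55 and 1.55). Smooth muscle myosin myh11b fell from 3.79 ± 0.546 to 0.857 ± 0.277 FPKM. Of 11 skeletal muscle markers, 8 rose, 0 fell and 3 did not pass, as when adjusted over the list alone (median 0.44, adjusted p = 0.00147; adjusted p = 0.578 with an estimated correlation). The actin ACTA1 went from 217 ± 37.6 to 699 ± 53.4 FPKM and tnnc2, of fast muscle, from 1.85 ± 0.358 to 13.3 ± 1.06. Without suppressed replicate 1, 5 of them passed. Of 7 kidney and interrenal markers, 4 rose (cdh17, nphs1, lrp2a and cyp21a2), 0 fell and 3 did not pass, as when adjusted over the list alone (median 0.58, adjusted p = 0.0335; adjusted p = 0.578 with an estimated correlation). That list lost its call without suppressed replicate 1, 2 or 3 (adjusted p up to 0.261), with 2 members past the test without replicate 1 or 2, and cyp21a2 lost its call without control replicate 1 or 2 or suppressed replicate 1 or 2 (up to 0.113). In all, cdh17 held 24 counts in control and 1988 in suppressed ovary, so it met the FPKM filter only with all 3 suppressed libraries. Without any of them it left the list, which by itself could end the call.

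Of 20 leukocyte markers in ovary, 8 fell, 1 rose (a copy of CTSS, ENSONIG00000006671 being another copy that fell) and 11 did not pass, with 10 and 2 when adjusted over the list alone (median -0.63, adjusted p = 0.136). The macrophage receptor csf1rb fell from 6.09 ± 1.74 to 2.03 ± 0.410 FPKM. Control replicate 1 had a median of -0.53 for this list against 0.28 and 0.27 in the other controls, and without it the list had an adjusted p of 0.00132 (adjusted p = 0.597 with an estimated correlation), while 5 members passed without suppressed replicate 1. In ovary too, only 6 of 30 liver markers and 3 of 15 exocrine pancreas and intestine markers in the table met the FPKM filter. Of these 6 liver markers, 4 fell, 2 rose (a copy of C3, and c5) and 0 did not pass, as when adjusted over the list alone (median -1.88, adjusted p = 0.136). The apolipoprotein genes apoeb (from 2604 ± 1049 to 260.3 ± 63.8 FPKM) and apoa1a (from 258 ± 105 to 10.8 ± 1.97) fell, while the complement gene C3 rose from 0.0578 ± 0.0450 to 5.27 ± 0.679 FPKM. The 3 exocrine pancreas and intestine markers cpa4, cdx1b and a copy of FABP6 fell, as when adjusted over the list alone (median -1.38, adjusted p = 0.128). The carboxypeptidase gene cpa4 went from 22.3 ± 11.3 to 1.28 ± 0.504 FPKM. The liver list passed its test without control replicate 1 (adjusted p = 0.00767) or without any 1 suppressed library, and the pancreas list without control replicate 1 (0.0164) or suppressed replicate 3 (0.0392). With an estimated correlation these calls were lost (adjusted p of at least 0.424 for liver, and 0.565 and 0.709 for pancreas). Without 1 suppressed library C3, near 0 in the controls, fell below the FPKM filter. Those liver tests therefore lacked this rise, which by itself could make the list lower. The calls of cdx1b and FABP6 were lost without control replicate 2 or suppressed replicate 1 or 2, among others (up to 0.102 and 0.0914), each leaving 1 pancreas marker past the test, and 3 liver markers passed without control replicate 2 or 3 or suppressed replicate 1 or 3.

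Several ovary genes outside the lists were present under 1 label and near 0 under the other. The photoreceptor gene rd3 averaged 88.8 ± 2.42 FPKM in suppressed and 0.328 ± 0.214 in control ovary, and a copy of PLA2G12B averaged 18.3 ± 2.27 FPKM and was at 0 counts in all 3 controls, at least 726-fold higher. In the other direction, the stress peptide gene crhb stood at 0.206 ± 0.0493 against 54.4 ± 3.68 FPKM and txlnbb at 0.0130 ± 0.0223 against 37.1 ± 1.57. A copy of the carbonic anhydrase CA4 was at 0 counts in all 3 suppressed libraries and at 29.4 ± 1.89 FPKM in control ovary, at least 2182-fold lower. These calls held in every fit that tested them. All of these genes met the FPKM filter only through the 3 libraries of the higher group. Those fits therefore left out only libraries of the lower group, where a call could hardly be lost. Without each library in turn between 3141 and 4069 genes passed in ovary. Under scaling by total count 1699 genes were higher and 3014 lower.

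Changes in the tissues overlapped more than chance gives in the same direction. Of 11586 genes tested in both, 202 were higher in both (99.8 expected, Fisher's exact p = 4.62e-26, adjusted over 4 tests 1.85e-25) and 193 were lower in both (94.8 expected, p = 5.89e-25, adjusted 1.18e-24). Genes higher in testis and lower in ovary numbered 77 (95.8 expected, Fisher's exact p = 0.0333) and the reverse 72 (98.7 expected, p = 0.00210, adjusted 0.00280), fewer than chance gives. These p-values treat genes as independent, which they are not, and do not measure the spread between libraries. Of the 544 called in both, 395 (72.6%) had the same sign, among them ddx4, dcn, stab2, rrm1 and ccne2, higher in both, and agt, psmb8a, jun and fam188b2, lower in both. Across these genes, which are not independent replicates, the log2 changes had a Pearson r of 0.423 and a Spearman rho of 0.479, and across all 11586 genes 0.245 and 0.218. Without 1 library the number called in both with the same sign ran from 78 (without testis control replicate 2) to 669 (without suppressed testis replicate 3).

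**Figure D3:**
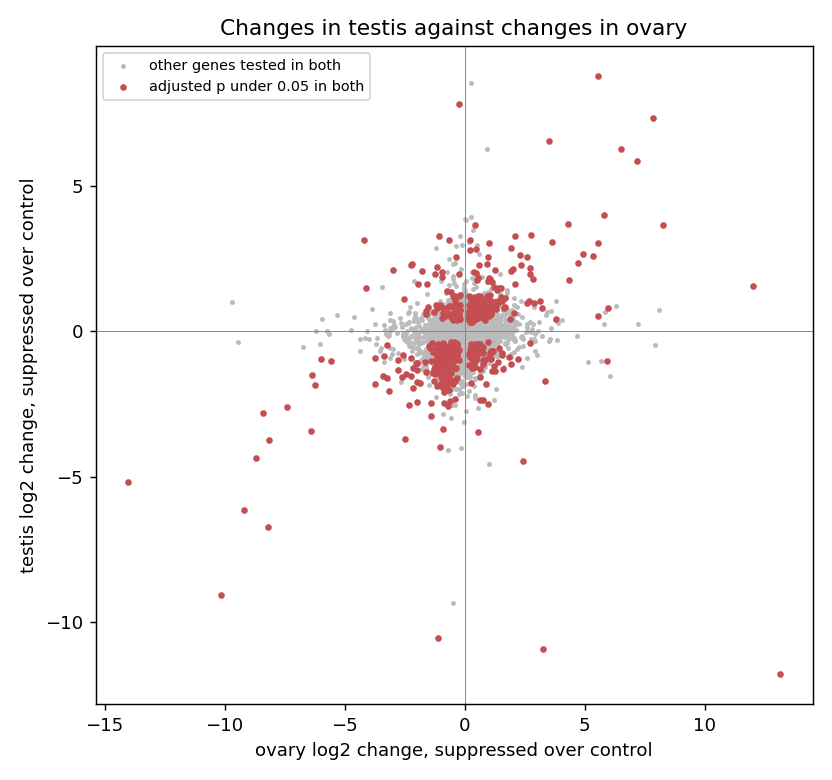
Log2 change between labels in testis (vertical) against ovary (horizontal) for the 11586 genes tested in both, with the 544 called in both in red. Of those 544, 395 lay in the quadrants of the same sign; fitted values of genes at 0 counts depend on the prior count.

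The change between labels also differed between testis and ovary for 2381 of 15382 genes tested by the interaction, of which 1127 were higher and 1254 lower in testis relative to ovary. Cholesterol synthesis genes differed as a group (26 tested; 4 higher in testis relative to ovary, 0 lower and 22 not past, as when adjusted over the list alone; median 0.29, adjusted p = 0.0109; adjusted p = 0.746 with an estimated correlation). The lipoprotein receptor ldlra rose in testis from 9.61 ± 0.918 to 14.1 ± 1.95 FPKM and fell in ovary from 16 ± 1.39 to 6.25 ± 0.417 (SD, n = 3; interaction log2 1.92, SE 0.15, adjusted p = 8.49e-06), and fdft1 had an interaction of 1.41 (adjusted p = 1.23e-05). Steroidogenesis and the cell cycle were not past this test (adjusted p = 0.0585 for each), nor was any other list. Single steroid genes were: star had an interaction log2 of 1.87 (SE 0.44, adjusted p = 0.0127), hsd3b1 one of 1.50 (adjusted p = 0.0307), hsd17b1, near the floor in testis at 0.300 against 0.0607 FPKM, one of 3.14 (adjusted p = 0.0134) and cyp19a1a one of 1.28 (adjusted p = 0.0382), each higher in testis relative to ovary. Like hsd17b1, cyp19a1a was far lower in control testis than in control ovary, as given below, so its testis change rests on low levels. For ddx4 the interaction was -0.46 (adjusted p = 0.0734) and for SF1 0.50 (adjusted p = 0.642). The germ line gene dnd1 fell in testis and rose in ovary (interaction -1.32, adjusted p = 0.000133), and clu fell by 2.46 more in testis (adjusted p = 0.000285). Without 1 library between 1672 and 3043 genes passed.

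Control testis was compared with control ovary for the tissue difference without the treatment. Of 14719 genes tested, 6487 were higher in testis and 6222 higher in ovary, and the groups did not overlap for 12954 (88.0%, where chance gives 10%). Among single genes higher in testis, star stood at 255 ± 53.0 against 3.19 ± 0.499 FPKM (SD, n = 3; log2 difference 6.13, adjusted p = 2.77e-09), cyp17a2 at 357 ± 128 against 6.26 ± 1.73 (5.64, adjusted p = 8.87e-08) and hsd11b2 at 55.7 ± 13.1 against 1.35 ± 0.202. SF1 was higher in testis by 2.47 (adjusted p = 4.2e-05), as were dmrt1 by 7.81 (adjusted p = 3.96e-10) and sycp3 by 7.0 (adjusted p = 4.5e-10). Among single genes higher in ovary, cyp19a1a had a difference of -6.80 (adjusted p = 4.84e-09), hsd17b1 of -10.09 and zar1 of -7.79 (adjusted p = 2.52e-10). Genes at 0 counts in control ovary included the kinase nek12, at least 2705-fold higher in testis, si:dkey-48j7.3 (at least 1891-fold), esamb (at least 1653-fold), a copy of kctd1 (at least 1625-fold) and ttc34 (at least 1368-fold). Genes at 0 counts in control testis included a copy of CA4, at least 1589-fold higher in ovary, bglap (at least 351-fold), synpr (at least 307-fold), ch25hl2 (at least 248-fold) and c8g (at least 182-fold). Without 1 library between 10193 and 11981 genes passed.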

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

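The tests of switch-like genes, with each gene counted once, of SF1 and of suppressed testis replicate 3 were chosen after their results were seen, and the bounds that would exclude more steroid-producing cells and too few reads were reworded after their values were known; the splits of the libraries were planned before. Each group had 3 libraries, so no library was tested for lying far from its group.

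The change between labels differed between testis and ovary, by the interaction test, for 2381 genes. Of 100 relabellings drawn within the tissues, the real one included, 1 gave as many, and the highest of the others gave 1223. This argues only against the case in which the labels made no difference in either tissue. Mixed groups carry any label difference as spread, so these draws do not test the interaction by itself. Exchanging the labels of the ovary alone, which was not among those drawn and tests the sum of both changes, gave 4132. In testis 1 of the 10 splits gave as many genes as the real 1571 (the highest other gave 1), in ovary 1 of 10 as many as the real 4510 (the highest other gave 1), and between control tissues 1 of 10 as many as the real 12709 (the highest other gave 0). Those 10 splits are too few for a share under 0.05.

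By the same test cholesterol synthesis differed between the tissues as a group (adjusted p = 0.0109; adjusted p = 0.746 with an estimated correlation), and 92 of 198 tested named genes differed. Genes called in opposite directions in the tissues included the lipoprotein receptors ldlra (interaction log2 1.92) and ldlrb (1.52), the apoptosis gene apaf1 (1.09), the macrophage receptor csf1rb (2.31) and the podocyte gene nphs1 (-1.42). Genes lower in both tissues by different amounts included apoeb (1.60) and agt (4.36). Among genes named for the size of the interaction, lbx1a (12.49), si:ch73-70c5.1 (9.76), txlnbb (9.07), si:zfos-1011f11.1 (8.79) and si:dkey-211g8.4 (8.06) were higher in testis relative to ovary. A copy of znf507 (-24.96), a copy of PLA2G12B (-18.44), and2 (-12.07), esamb (-9.55) and calcoco1b (-9.27) were lower. Several of these are at 0 counts in a group, and their fitted values depend on the prior count and are no bounds. Without suppressed testis replicate 3 txlnbb had an interaction of 5.58 (adjusted p = 0.970). The copy of znf507 was at 0 counts in suppressed testis and in control ovary, at least 521-fold lower in testis and at least 1054-fold higher in ovary under the suppressed label.

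Differences of at least 32-fold between labels occurred in 40 genes in testis and 86 in ovary, 9 of them shared; 68 of the 126 cases were higher and 58 lower in the suppressed libraries, and 37 were at 0 counts in the lower group. LSM3, rd3, agt and CA4 were among them. The level of the higher group would have given at least 107 counts in the lower group in each of the 126 cases. At most 2.98% of the count so expected was found. Since the cases were chosen at 32-fold and past the test, that choice largely set these values. They therefore do not test too few reads as a cause. A genetic difference between control and suppressed fish may contribute: of 51 genes tested in the other tissue 51% passed there in the same direction (exact 95% interval 36.6 to 65.2%) and 4 passed in the opposite one, which leaves it open. Reads moved between near-identical copies also stayed open, since genes named as copies were 1.51 times as frequent among these 117 genes as among tested genes (12.8 against 8.51%). Genes without a symbol made up 42.7% of them and 11.8% of tested genes, and a biological effect of the treatment was not separable from these.

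SF1 RNA was not lower in the testis libraries labelled SF1-suppressed. More steroid-producing cells might hide a lower level per cell, but the SF1 change minus the median change of the Leydig cell list was -0.0274 (-0.05, -0.16 and -0.43 in the 3 libraries), and since that list holds genes SF1 acts on, a value near 0 decides nothing. Reads from the introduced fragments could be counted as SF1, and the ovary log2 change of 0.0441 (SE 0.34) neither shows nor excludes this. A recovery of SF1 after the early treatment was not tested, nor was an exchange of the labels control and suppressed, which would reverse every direction given between them.

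In suppressed testis replicate 3, steroid and somatic genes were lower than in replicates 1 and 2. A lower share of somatic cells in that sample stayed open: 4 of 5 somatic lists had medians at least 0.5 log2 units lower (Leydig cell -1.56, stroma -2.17, endothelium -1.33, leukocyte -1.25), while Sertoli cell genes were lower by less (-0.41) and flagellum genes lay higher (0.46), but these lists make up the pattern and cannot decide on its cause. A shallower library was excluded, since its total of 47.3 M counts lay within the range of the other testis libraries. Cell share itself was not measured, and neither the treatment nor the sampling was tested as a cause of any difference in it.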

How the results depend on the processing

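The tests with limma on log2(FPKM + 1) and with DESeq2, the counts of list members without 1 library, the estimated correlation without 1 library, and for the overlap the replicate block, scaling by total count and no filter, were chosen after the data had been seen; the other alternatives were planned. The number of testis genes changed (1571 with edgeR) was 8534 in limma on log2 FPKM with weights per library. It was 276 with a block for the replicate number, 3030 in 1 fit over all 12 libraries, 2891 with DESeq2 and 696 with a minimum absolute log2 change of 1. Without 1 library it ran from 312 (without control replicate 2) to 2790 (without suppressed replicate 3). The number of ovary genes changed (4510) was 2868 in 1 fit over all libraries, which pools the spread of all groups, and 1098 with the minimum change. The number between control tissues (12709) stayed within 1.5 times of itself under every alternative run. The number of tissue by suppression interaction genes changed (2381) was 6810 in limma on log2 FPKM with weights per library and 1335 with the minimum change. Apart from the minimum change and the number of libraries, which limit the calls by construction, the cause was not tested. The block takes up degrees of freedom, and the labels do not pair libraries by number. Deviations from the group mean in control and suppressed libraries of the same number had correlations of -0.196, -0.00553 and -0.245 in testis. In ovary these were -0.0111, -0.0491 and -0.0962. Between unlike numbers they ran from -0.172 to 0.242. These values give no sign of a pairing, so calls lost with the block do not show that one was ignored.

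The SF1 change in testis (0.58 with edgeR) was 0.94 in limma on log2 FPKM with weights per library (adjusted p = 0.00038). Without 1 library, in edgeR, it ran from 0.34 to 0.97. Only without suppressed replicate 3 and with these weights was it past the test. In ovary it ran from -0.32 (without suppressed replicate 2) to 0.33 (without control replicate 3) and was not past the test under any alternative run. A copy of hsd17b7 had a testis change of -0.31 in limma on log2 FPKM with weights per library, past the test, against 0.01 with edgeR. Of genes changed in both tissues, 395 had the same sign, 63 with the replicate block and from 78 (without testis control replicate 2) to 669 (without suppressed testis replicate 3) without 1 library.

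Of gene lists, 7 passed in testis and 5 in ovary. With an estimated correlation in camera 0 and 0 passed (1 and 2 at an unadjusted p under 0.05), and 0 also did so without any 1 library, with fry 5 and 11, with its mixed form 21 and 22, and without 1 library from 4 to 7 and from 5 to 7. With an estimated correlation p rose even where the estimate lay below the preset 0.01. For the testis pancreas list it was -0.0484 (camera p from 0.00142 to 0.0322) and for the testis muscle list 0.00168 (from 0.00795 to 0.0503). The loss of these calls therefore did not come from correlated genes. For the other lists past the test the estimate lay above 0.01. Of the 7 testis lists fry kept liver and pancreas. It lost steroidogenesis (adjusted p = 0.0679), cell cycle (0.0957), Sertoli cell (0.0957), meiosis (0.144) and skeletal muscle (0.0532). Its other testis calls were cholesterol synthesis, apoptosis, and kidney and interrenal. In ovary fry kept all 5 lists. Among named genes, leaving out 1 library left 1169 comparisons unchanged, ended a call in 214 and added one in 7. Unchanged means past the test in both fits in the same direction, or past it in neither with a shift within the SE. A further 8 were past it in neither and shifted by more. The replicate block ended 55 calls and 1 fit over all libraries 33. In limma on log2 FPKM, quantile normalisation ended 22, no mean-variance trend 20 and the other pseudocount 18. Further, limma on log2(FPKM + 1) ended 15, scaling by total count 8, weights per library 5, no filter 3, the filter at an FPKM of 5 2 and DESeq2 2. With median-of-ratios scaling all 254 comparisons, those of genes not past the test included, were unchanged. Weights per library added 19 calls, DESeq2 5 (all testis steroidogenesis genes), 1 fit over all libraries 4 and quantile normalisation 3.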

Other observations

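Lists of other cell types and of stress were also tested, with labels compared within each tissue. Of 20 apoptosis genes in testis, 2 rose (apaf1 and a copy of cycsb), 0 fell and 18 did not pass, as when adjusted over the list alone (median 0.17, adjusted p = 0.210). Both calls were lost without any 1 control library or suppressed replicate 2 (adjusted p up to 0.0962 and 0.172). In ovary 3 of 20 rose (bcl2l1, birc2 and casp8), 4 fell (among them tnfrsf1a, apaf1 and aifm1) and 13 did not pass, as when adjusted over the list alone (median -0.06, adjusted p = 0.620). Without ovary suppressed replicate 3, 4 of these passed. Of 18 interferon response genes in testis, psmb8a, a proteasome subunit, fell from 26.3 ± 3.65 to 4.27 ± 2.25 FPKM, 0 rose and 17 did not pass, as when adjusted over the list alone (median -0.24, adjusted p = 0.291). In ovary it fell from 15.6 ± 1.64 to 2.98 ± 0.502 FPKM. There irf9 and tlr9 fell too, usp18 rose and 9 of 13 did not pass, as when adjusted over the list alone (median -0.10, adjusted p = 0.398). The calls of irf9 and tlr9 were lost without suppressed replicate 1 or 3, among others (up to 0.134 and 0.15), each leaving 2 members past the test.

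Of 19 endothelium genes in testis, stab2 and egfl7 rose, 0 fell and 17 did not pass, with 3 and 0 when adjusted over the list alone (median 0.07, adjusted p = 0.659). The call of egfl7 was lost without any 1 control library or suppressed replicate 2 (up to 0.125), and 6 members passed without suppressed replicate 3. In ovary aplnrb, stab2 and fli1b rose, flt4 and kdr fell and 9 of 14 did not pass, as when adjusted over the list alone (median 0.19, mean -0.02, test negative, adjusted p = 0.951). The lymphatic receptor flt4 went from 11.7 ± 0.488 to 1.27 ± 0.204 FPKM. The call of kdr was lost without suppressed replicate 1 (0.0586), which left 2 members past the test, and 3 passed without suppressed replicate 3. Of 10 adipocyte genes in testis, dgat2 and fabp11b rose, lpl fell and 7 did not pass, as when adjusted over the list alone (median 0.10, adjusted p = 0.560). Each of the 3 calls was lost without any 1 control library (up to 0.116, 0.116 and 0.146). In ovary dgat2 and plin2 rose, fabp11a, lpl and pparg fell and 4 of 9 did not pass, as when adjusted over the list alone (median 0.07, mean -0.39, test positive, adjusted p = 0.899). The lipid carrier fabp11a went from 795 ± 339 to 103 ± 13.9 FPKM, and the calls of lpl and pparg were lost without control replicate 3 or suppressed replicate 1 or 3 (up to 0.0579 and 0.0612), each leaving 3 members past the test.

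Of 16 leukocyte markers in testis, csf1rb rose from 8.59 ± 0.548 to 14.2 ± 1.48 FPKM, 0 fell and 15 did not pass, as when adjusted over the list alone; the median was -0.10 and the mean -0.05 while the test was positive (adjusted p = 0.932), and 5 members passed without suppressed replicate 3. Of 7 erythrocyte markers there, alas2, of haem synthesis, fell from 6.83 ± 3.27 to 2.47 ± 0.474 FPKM, 0 rose and 6 did not pass, with 2 falls when adjusted over the list alone (median -0.92, adjusted p = 0.136). That call was lost without any library but suppressed replicate 3 (up to 0.115), without which 4 members passed, and the list passed without control replicate 3 (adjusted p = 0.0439; adjusted p = 0.777 with an estimated correlation). Of 5 neuron and glia markers in testis 0 passed (median 0.08, adjusted p = 0.863).

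Renin (ren, ENSONIG00000017285) rose in suppressed testis from 0.226 ± 0.170 to 25.3 ± 12.8 FPKM (log2 change 6.93, adjusted p = 0.00141). Its substrate angiotensinogen (agt) fell from 8.14 ± 1.44 to 0.551 ± 0.211 FPKM in testis and from 18.3 ± 2.66 to 0.0527 ± 0.0243 in ovary. All of these calls held in every fit that tested them. Both genes were under 1 FPKM in the lower group, so these fits left out only libraries of that group. The libraries behind the high levels, with their wide spread for ren, were never left out. The change of agt differed between the tissues (interaction log2 4.36, adjusted p = 0.000158).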
